A study of Solanum lycopersicum with 12 samples.

How the data were processed

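RNA of whole tomato seedlings (*Solanum lycopersicum*, cultivar Arka Saurabh) was extracted as total RNA and measured by bulk RNA sequencing in 12 libraries, 3 in each of 4 groups. Per the labels' protocols, germinated seeds were kept for 3 h in a liquid culture of a fungal endophyte or, for the controls, in water. They were then grown between sheets of germination paper, wetted for the salt groups with 130 mM NaCl, and roots and shoots were collected after 7 days. The fungus is named K23, a strain of *Fusarium incarnatum* that lives inside plant tissue. The groups are called control, salt, K23, and K23 plus salt. The labels do not say that the libraries of a group came from separate plants or cultures, so the p-values measure only the spread between these samples, which may be technical.

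The submitters' processing notes name FastQC, Trimmomatic, STAR, bedtools and DESeq2, with no version, order or role. The genome build is not given in the sources used here, and neither is whether counting used the strand. The authors deposited 1 table of raw read counts with 1 line per protein isoform. Per its headers, each line has a start, a stop and a protein name. The headers do not say what the span covers. For 79 of 86 plastid genes its length was a multiple of 3, so it was taken to run from coding start to coding stop. Counts over such a span would include introns and leave out untranslated regions, which the sources used here do not state. The table held 37603 lines for 25555 genes. Isoforms of a gene share reads, so the line with the most counts stood for the gene and nothing was summed. For 194 of 6099 genes with several lines, these lines differed by more than 1.5-fold in total. A span overlapped that of another gene for 234 genes, whose reads cannot be told apart without strand; no gene named in the text was among them. Reads of near-identical family members, such as the clustered xyloglucan endotransglucosylase genes, may have been split between copies by the authors' counting. Symbols and chromosome numbers came from a reference gene table of assembly SLM_r2.1, in which 24234 gene identifiers matched; start and stop are those of the authors' count table.

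The authors also deposited 8 lists of log2 fold changes, an up and a down list for each of 4 pairs of groups, with no p-values and only sizes of 2 or more. Their values are the first named group over the second, so a gene in an up list of control against salt was lower in salt. These lists were used only for comparison with the refit.

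Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 4 groups, which left 22035, and libraries were scaled by TMM. One quasi-likelihood model with a mean per group was fitted to all 12 libraries, which share 1 estimate of the spread; the biological coefficient of variation was 22.7%. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, with a threshold of 0.05. Levels are CPM, the counts of a gene scaled to a common TMM-corrected library total, given as mean ± SD over 3 libraries, and log2 fold changes are given ± SE, taken as the size of the change over the square root of its F statistic. A count of 3, taken as the floor of 1 library, corresponds to 0.0515 to 0.0877 CPM. Library totals ran from 34193409 to 58264222 counts, and all groups overlapped in depth. In data simulated from the mean levels, spreads and totals of these libraries, with 200 genes of at least 1 CPM changed, the share of 2-fold changes recovered was 55% for salt without K23, 58% for salt with K23, 54% for K23 without salt, 64% for K23 with salt and 28% for the interaction. The shares for 4-fold changes were 96%, 94%, 91%, 94% and 79%, and between 2 and 13 unchanged genes were called. A further 60 genes were shifted by 0.5 on the log2 scale and not counted as unchanged. Genes were drawn independently, without the differences between real libraries that run across many genes, so these numbers may not carry over to the real data.

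The 5 comparisons were salt against control, K23 plus salt against K23, K23 against control, K23 plus salt against salt, and the interaction, which is the difference between both salt effects. Before the data were examined, 27 gene lists were fixed as word searches of product descriptions. They were nuclear photosynthesis genes (a marker of shoot tissue), root tissue markers, and seed storage and oil body genes (markers of retained seed reserves). They were also LEA (late embryogenesis abundant) proteins and dehydrins, abscisic acid, osmolyte synthesis, sodium and potassium transport, aquaporin, heat shock, antioxidant enzyme, class III peroxidase, glutathione S-transferase, pathogenesis-related, fungal recognition and resistance receptor, jasmonate, protease inhibitor and wound, ethylene, auxin, gibberellin, cell wall loosening and remodelling, phenylpropanoid and flavonoid, WRKY, NAC, cell cycle and histone, cytosolic ribosomal protein, sugar transport and sucrose cleavage, and phosphate and iron supply genes. Some members only share a word with a list, such as GEM-like proteins, basic 7S globulins and oxidase homologs. Each list was tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, two-sided, against the other genes, and adjusted over the 27 lists. A camera test with the correlation estimated per list and fry, which asks whether a list moved on balance one way without comparing it to other genes, were alternatives. A count adjusted over the list alone uses only the p-values of its members.

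Genes were named by a rule fixed at the same time. It asked for an adjusted p under the threshold, no overlap between the libraries of the compared groups, a mean of at least 5 CPM in 1 of them, and a described product. Of such genes it took the 6 higher and 6 lower with the largest change. It then took 2 called members of up to 8 passing lists in the direction of the list, and for the other lists the called member with the smallest adjusted p in each direction. For the interaction it took called genes, up to 10. A lack of overlap arises by chance in 10% of comparisons of 3 against 3 libraries. Of the genes tested, 4207 are described as uncharacterized and were not named.

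Alternatives were DESeq2 1.42.0, RLE scaling, library totals alone, no filter and a stricter filter, a fit on the compared groups only, a log2 fold change of at least 1, and leaving out each library in turn. Alternatives chosen after seeing the data were the line with the fewest counts per gene, no plastid or mitochondrial genes, and lists without members that only share a word. For the named genes, both filters and the fit on the compared groups only were added then too. No pair of libraries in a group was near identical (chi-square per degree of freedom 23.51 to 122.12). The labels call the K23 seedlings colonised. Fungal reads were not analysed here, so the degree of colonisation is not known.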

Results

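Transcript levels were measured in tomato seedlings grown with or without 130 mM NaCl after contact with the fungus K23 or with water, to ask how seedlings treated with the fungus respond to salt. Each of the 4 groups held 3 libraries, which are called by the number in their column name: controls 6, 7 and 8, salt 51, 52 and 53, K23 36, 37 and 38, and K23 plus salt 81, 82 and 83. Library totals were 34193409 to 36437876 counts in the controls, 34399026 to 42463233 in salt, 35876418 to 58264222 in K23 and 34971607 to 43620907 in K23 plus salt. The 10 most abundant genes of a library took 2.95 to 5.52% of its counts. Plastid genes took 0.276 to 0.564% in the controls, 0.227 to 1.054% in salt, 0.125 to 0.169% in K23 and 0.179 to 0.234% in K23 plus salt. Most of this share lay on the rps12 line, which alone took 0.213 to 0.483%, 0.184 to 0.97%, 0.09 to 0.12% and 0.123 to 0.188% in the same order. The first principal component held 46.7% of the variance and parted the libraries with salt, at 30.39 to 64.4, from those without, at −87.42 to −22.78. The second held 13.6%. Nuclear photosynthesis genes, a marker of shoot tissue, varied within groups. Their median log2 level, relative to the mean of the 12 libraries, was −0.92, 0.16 and 0.52 in controls 6, 7 and 8, and 0.02, 0.70 and 0.66 in salt 51, 52 and 53. It was −0.58, −0.06 and −1.23 in K23 36, 37 and 38, and 0.46, 0.35 and −0.02 in K23 plus salt 81, 82 and 83.

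**Figure D1:**
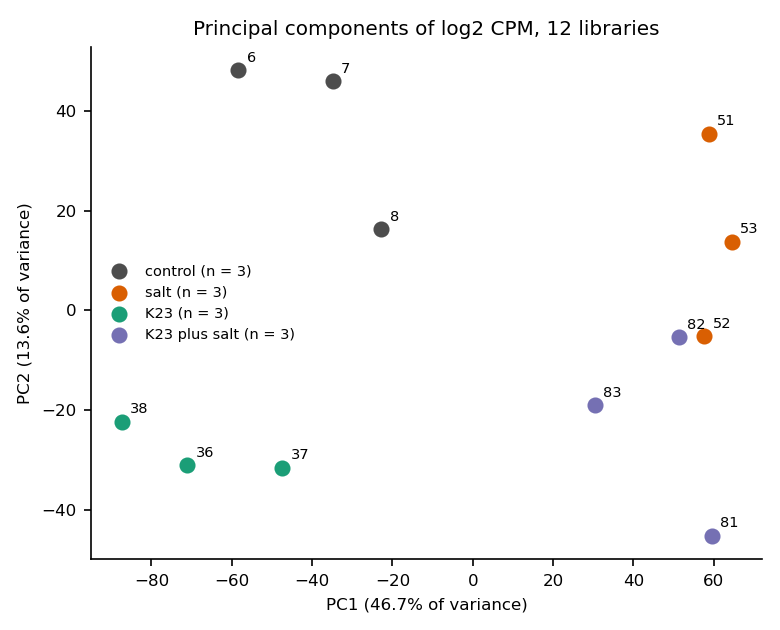
Scores of the 12 libraries on the first principal component (46.7% of the variance) and the second (13.6%) of log2 CPM, 1 point per library, with the 4 groups marked. The libraries with salt lie at 30.39 or above on the first component and those without at −22.78 or below.

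Salt without K23 raised a wax ester synthesis gene and a proline synthesis gene and lowered a proline degradation gene. O-acyltransferase WSD1 (LOC101251623), an enzyme of wax ester synthesis, rose from 0.377 ± 0.375 to 14.5 ± 6.65 CPM (mean ± SD, n = 3 in each group throughout), a log2 fold change of 5.24 ± 0.80 (SE, adjusted p = 0.00112). The lipid-transfer protein LE16 rose by 4.30 ± 0.51 (adjusted p = 0.000261), a MYB41-like factor (LOC101252700) by 3.77 ± 0.64 (adjusted p = 0.00196), and the sugar transporter SWEET1-like (LOC101259239) from 1.88 ± 0.599 to 28.7 ± 0.923 CPM. The proline synthesis enzyme delta-1-pyrroline-5-carboxylate synthase (LOC101244293; chromosome 6, 17990347 to 17998948) rose from 25.3 ± 3.54 to 119 ± 26.6 CPM (2.24 ± 0.19, adjusted p = 4.65e-05). Proline dehydrogenase (PDH; chromosome 2, 52014175 to 52015927), which degrades proline, fell from 142 ± 18.2 to 19.8 ± 5.97 CPM (−2.84 ± 0.21, adjusted p = 1.86e-05).

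In all, 2371 of 22035 genes rose and 2337 fell between salt and control (edgeR, adjusted p under 0.05), with a median SE of 0.197, 841 and 1194 of them changed by at least 1 on the log2 scale. The other genes with the largest rise were a nuclear factor Y subunit A-7-like gene (LOC101261974, 4.24 ± 0.26) and a polygalacturonase (LOC101246713, 3.85 ± 0.42), a class of enzyme that cleaves pectin. The largest fall was that of an inositol polyphosphate 5-phosphatase (LOC101244493), from 16.2 ± 1.48 to 0.171 ± 0.0422 CPM (−6.52 ± 0.36, adjusted p = 9.73e-06). It was followed by a hyoscyamine 6-dioxygenase-like gene (LOC101246190, −5.72 ± 1.13), a leucine-rich repeat receptor kinase (LOC101266996, −5.67 ± 0.52), a resveratrol O-methyltransferase-like gene (LOC101265317, −5.48 ± 0.97) and cytochrome P450 94B3-like (LOC101263302, −5.46 ± 1.32, adjusted p = 0.0131). The abscisic acid receptor gene PYL4-like (LOC101261414) fell from 11.2 ± 2.41 to 0.269 ± 0.07 CPM (−5.38 ± 0.69). The SD of LOC101263302 in the controls, 11.6 CPM, exceeded its mean of 7.66, its change was only −2.48 without control 7, and its call was lost without salt 51 (adjusted p = 0.0524) or salt 53 (adjusted p = 0.0541). The number of genes called fell from 4708 to 3071 without control 6 and to 3084 without salt 53.

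**Figure D2:**
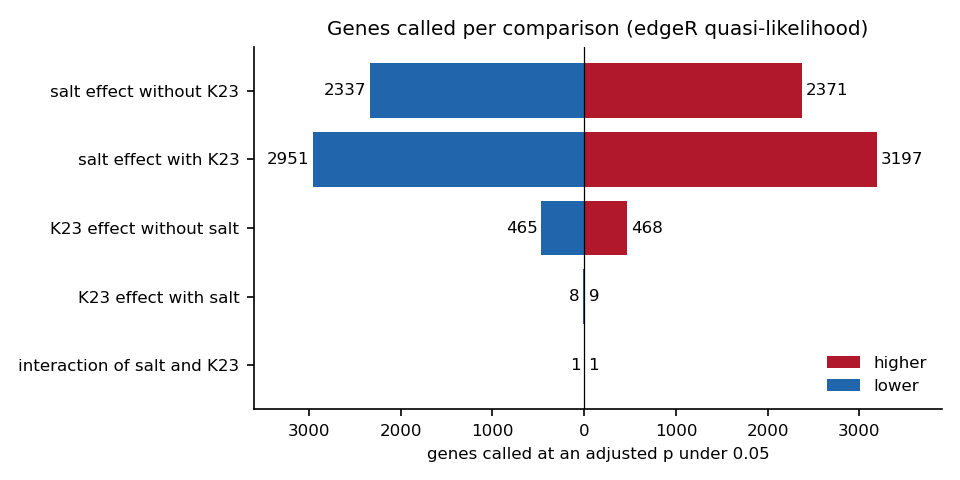
Numbers of genes higher and lower at an adjusted p under 0.05 in each of the 5 comparisons (edgeR, 22035 genes tested). They run from 3197 higher and 2951 lower for salt with K23 to 1 and 1 for the interaction.

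Of the 27 gene lists, 10 passed lower and 4 higher (camera, preset correlation); none passed with the correlation estimated per list, where the smallest adjusted p was 0.0509. Of 70 WRKY factors, regulators of defence and stress genes, 29 fell and 4 rose (35 and 5 adjusted over the list alone). The median was −0.77, with adjusted p = 3.78e-08, and adjusted p = 0.231 with an estimated correlation. WRKY70 (LOC101256570) fell from 28.8 ± 9.54 to 2.07 ± 0.901 CPM and SlWRKY72b from 12.8 ± 7.53 to 0.593 ± 0.26. Of 221 fungal recognition and resistance receptor genes, 48 fell and 15 rose (49 and 16 adjusted over the list alone). The median was −0.16, with adjusted p = 0.00128, and adjusted p = 0.24 with an estimated correlation. The late blight resistance homologs R1B-16 (LOC101249231) and R1A-3 (LOC101247808) fell by 2.22 and 1.91 on the log2 scale. Of 123 pathogenesis-related genes, 24 fell and 8 rose (28 and 9 adjusted over the list alone). The median was −0.18, with adjusted p = 0.0215, and adjusted p = 0.301 with an estimated correlation. PR-5 (LOC101264959), a thaumatin-like protein, fell from 914 ± 284 to 73.1 ± 38.9 CPM, while a PR-1 gene (LOC101267538) rose from 1.57 ± 0.558 to 11.4 ± 1.84. Of 182 ethylene genes, 39 fell and 5 rose (40 and 6 adjusted over the list alone). The median was −0.30, with adjusted p = 0.00128, and adjusted p = 0.0509 with an estimated correlation. Ethylene-responsive factor 3 (LOC101249309) fell by 0.90, and an ACC oxidase homolog (LOC101245697), which shares the name of the enzyme of the last step of ethylene synthesis, by 3.53. Of 46 jasmonate genes, 11 fell and 3 rose (13 and 3 adjusted over the list alone). The median was −0.30, with adjusted p = 0.0221, and adjusted p = 0.231 with an estimated correlation. Examples were opr2 at −2.53 ± 0.29 and LEJA1 at 0.98 ± 0.18. Of 43 protease inhibitor and wound genes, 8 fell and 1 rose (the same counts adjusted over the list alone). The median was −0.83, with adjusted p = 0.00505, and adjusted p = 0.231 with an estimated correlation. Examples were a type-2 proteinase inhibitor (LOC109119847, −2.19 ± 0.34) and a wound-induced basic protein (LOC101251692, −0.55 ± 0.10). Of these lists, the pathogenesis-related call was lost without control 8 (adjusted p = 0.0565) and the jasmonate call without control 8 (adjusted p = 0.0726) or salt 51 (adjusted p = 0.0507).

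Of 95 class III peroxidases, secreted enzymes of the cell wall, 24 fell and 6 rose (24 and 6 adjusted over the list alone). The median was −0.30, with adjusted p = 0.00331, and adjusted p = 0.304 with an estimated correlation. Peroxidase 70-like (LOC101268440) fell from 28.1 ± 1.47 to 6.15 ± 0.859 CPM and peroxidase 51 (LOC101244162) from 23.1 ± 3.7 to 7.32 ± 1.51. Of 55 glutathione S-transferases, detoxifying enzymes, 13 fell and 2 rose (16 and 2 adjusted over the list alone). The median was −0.47, with adjusted p = 0.00331, and adjusted p = 0.273 with an estimated correlation. Examples were GST 23 (LOC101258000) at −0.58 ± 0.10 and LOC101266750 at −1.85 ± 0.32. Of 66 abscisic acid genes, 17 fell and 9 rose (18 and 10 adjusted over the list alone). The median was −0.16, with adjusted p = 0.00531, and adjusted p = 0.231 with an estimated correlation. The receptor gene PYL4 (LOC101250944) fell from 46.7 ± 1.28 to 10.5 ± 1.1 CPM. Of 219 cytosolic ribosomal protein genes, 31 fell and 2 rose (0 and 0 adjusted over the list alone). The median was −0.30, with adjusted p = 5.77e-07, and adjusted p = 0.646 with an estimated correlation. Examples were L35 (LOC101256286) at −0.62 ± 0.13 and L40 (LOC101244464) at −0.52 ± 0.12. The lists that passed higher were auxin, antioxidant, heat shock and photosynthesis genes. Of 152 auxin genes, 35 rose and 13 fell (40 and 16 adjusted over the list alone). The median was 0.33, with adjusted p = 0.0134, and adjusted p = 0.495 with an estimated correlation. The auxin-induced ARG2 (LOC544187) rose from 471 ± 136 to 1610 ± 359 CPM. Of 41 antioxidant enzymes, 10 rose and 1 fell (10 and 2 adjusted over the list alone). The median was 0.30, with adjusted p = 0.0062, and adjusted p = 0.231 with an estimated correlation. An example was cytosolic ascorbate peroxidase 2 (LOC101258987) at 1.08 ± 0.15. Of 84 heat shock genes, 18 rose and 5 fell (18 and 5 adjusted over the list alone). The median was 0.16, with adjusted p = 0.0221, and adjusted p = 0.535 with an estimated correlation. An example was heat stress factor A-2-like (LOC101266046) at 1.67 ± 0.21. Of 67 photosynthesis genes, 7 rose and 1 fell (2 and 0 adjusted over the list alone). The median was 0.47, with adjusted p = 0.000818, and adjusted p = 0.774 with an estimated correlation. Examples were PSB27-H2 (LOC101252922) at 1.03 ± 0.18 and PHOTOSYSTEM I ASSEMBLY 2 (LOC101267437) at 0.81 ± 0.16. This shift of a shoot marker accompanied each of the other lists. The calls of photosynthesis (adjusted p = 0.172) and auxin genes (adjusted p = 0.0584) were lost without control 6, and that of heat shock genes without control 7 (adjusted p = 0.069) or control 8 (adjusted p = 0.0726).

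The other 13 lists did not pass. Seed storage and oil body genes, markers of retained seed reserves, had 4 higher and 8 lower of 48 (median −0.02, adjusted p = 0.312), and NAC factors 2 and 9 of 53 (median −0.14, adjusted p = 0.272). Osmolyte genes had 9 and 3 of 34 (median 0.10, adjusted p = 0.474). Sodium and potassium transport genes had 8 and 8 of 64 (median −0.04, adjusted p = 0.958), among them the potassium channel genes AKT2/3-like (LOC101263942, 1.31 ± 0.15) and LKT1 (−1.72 ± 0.17). Cell wall genes had 32 and 32 of 316 (median 0.13, adjusted p = 0.72), with exp11 of the wall-loosening expansins at 2.16 ± 0.21. Phenylpropanoid genes had 8 and 16 of 115 (median −0.04, adjusted p = 0.597), cell cycle and histone genes 14 and 13 of 190 (median −0.10, adjusted p = 0.627), and sugar genes 9 and 12 of 73 (median 0.06, adjusted p = 0.848). In the other lists the median, mean and test differed in sign. These were root tissue markers with 7 and 6 of 61 (median −0.03, mean 0, adjusted p = 0.958), LEA genes with 3 and 5 of 36 (median 0.06, mean 0.21, test lower, adjusted p = 0.848) and aquaporins with 3 and 5 of 32 (median 0.03, mean 0.07, test lower, adjusted p = 0.866). They were also gibberellin genes with 3 and 3 of 34 (median −0.11, mean 0.11, test lower, adjusted p = 0.938) and phosphate and iron genes with 9 and 16 of 69 (median 0.01, mean −0.15, test lower, adjusted p = 0.201). Adjusted over the list alone, the higher and lower counts in the same order were 5 and 9, 2 and 9, 11 and 5, 8 and 8, 31 and 32, 8 and 15, 12 and 9, 12 and 14, 8 and 7, 3 and 5, 4 and 5, 3 and 3, and 11 and 18.

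**Figure D3:**
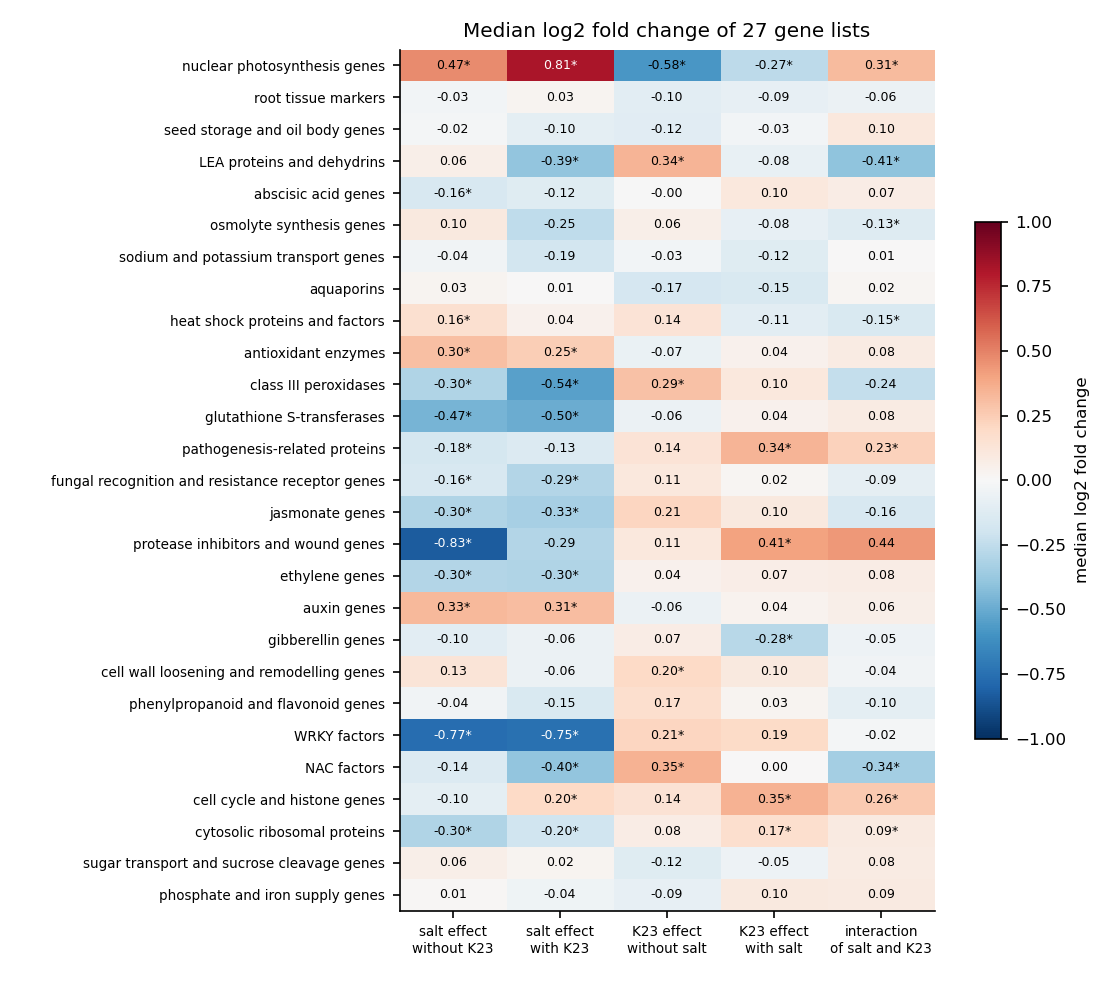
Median log2 fold change of the 27 gene lists in each of the 5 comparisons, as a heat map with an asterisk where the camera test passed at an adjusted p under 0.05 with the preset correlation. WRKY factors stood at −0.77 and −0.75 in the salt comparisons, without and with K23.

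In seedlings with K23, salt changed many of the same genes, and 3 of the largest falls were of single genes related to defence. The ethylene-responsive factor ERF016-like (LOC101268766) stood at 14.7 ± 5.02 CPM in K23 and 0.0673 ± 0.0101 in K23 plus salt (−7.70 ± 0.93, adjusted p = 0.000297). The latter mean lies below the floor of 3 counts, 0.0688 to 0.0858 CPM in these libraries, so the size of this fall is uncertain. The elicitor-responsive ubiquitin ligase gene CMPG1 fell from 45.3 ± 17.9 to 0.611 ± 0.246 CPM (−6.22 ± 0.83, adjusted p = 0.000512) and the resistance protein gene CSA1 (LOC101244742) from 25.8 ± 21.1 to 0.137 ± 0.0766. A glycine-rich protein gene (LOC101245699) rose from 0.865 ± 0.636 to 65.5 ± 26 CPM (6.28 ± 0.89, adjusted p = 0.000708). A salicylate carboxymethyltransferase-like gene (LOC101257111) rose from 0.713 ± 0.068 to 18.5 ± 7.03 CPM (4.70 ± 0.39, adjusted p = 4.57e-05).

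There were 3197 genes higher and 2951 lower (edgeR, median SE 0.196), 882 and 1517 of them by at least 1 on the log2 scale. The other large rises were WSD1 (LOC101251623, 4.22 ± 0.73), LE16 (3.96 ± 0.47), aquaporin TIP3-2-like (LOC101251154, 3.77 ± 0.88), a water channel of the vacuole membrane, and a two-pore potassium channel gene (LOC101246023, 3.67 ± 0.33). The other large falls were MYB14-like (LOC109120722, −6.46 ± 1.27), the subtilisin-like protease SBT1.7 (LOC778308, −6.16 ± 0.79) and ERF020-like (LOC101257505), which had 6.77 ± 4.69 CPM in K23 and 0.0187 ± 0.0323 in K23 plus salt, below the floor of 3 counts. The call of ERF020-like was lost without K23 plus salt 81 (adjusted p = 0.0607), 82 (0.0633) or 83 (0.0529). The proline genes moved as without K23, with LOC101244293 at 2.47 ± 0.19 and PDH at −2.37 ± 0.20. The number of genes called fell from 6148 to 4080 without K23 36 and to 3655 without K23 38.

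For salt with K23, 9 lists passed lower and 4 higher, none with an estimated correlation (smallest adjusted p = 0.0986). A fall here may also come from a high level in the K23 libraries, which the K23 effect without salt shares. Of 70 WRKY factors 32 fell and 3 rose (37 and 3 adjusted over the list alone). The median was −0.75, with adjusted p = 1.8e-08, and adjusted p = 0.178 with an estimated correlation. WRKY48 (LOC101264826) went from 15.2 ± 6.12 to 1.84 ± 0.563 CPM. Of 95 class III peroxidases 28 fell and 10 rose (28 and 10 adjusted over the list alone). The median was −0.54, with adjusted p = 4.16e-05, and adjusted p = 0.178 with an estimated correlation. An example was peroxidase 25 (LOC101267376) at −2.82 ± 0.26. Of 221 recognition and resistance genes 61 fell and 16 rose (62 and 17 adjusted over the list alone). The median was −0.29, with adjusted p = 4.16e-05, and adjusted p = 0.143 with an estimated correlation. NAC factors fell in 14 of 53 and rose in 1 (14 and 1 adjusted over the list alone). The median was −0.40, with adjusted p = 0.00116, and adjusted p = 0.143 with an estimated correlation. NAC22 (LOC101267943) went from 44.8 ± 8.75 to 3.71 ± 2.5 CPM. Ethylene genes fell in 44 of 182 and rose in 13 (44 and 13 adjusted over the list alone, median −0.30, adjusted p = 0.00575, and adjusted p = 0.0986 with an estimated correlation), while jasmonate genes fell in 13 of 46 and rose in 4 (15 and 4 adjusted over the list alone, median −0.33, adjusted p = 0.0119, and adjusted p = 0.143 with an estimated correlation). Glutathione S-transferases fell in 14 of 55 and rose in 7 (18 and 8 adjusted over the list alone). The median was −0.50, with adjusted p = 0.0147, and adjusted p = 0.412 with an estimated correlation. LEA genes fell in 8 of 36 and rose in 0 (8 and 0 adjusted over the list alone, median −0.39, adjusted p = 0.0235, and adjusted p = 0.412 with an estimated correlation), but the call was lost without members that only share a word, such as GEM-like protein 5 (LOC101259275, adjusted p = 0.215 for the list). Ribosomal protein genes fell in 16 of 219 and rose in 4 (0 and 0 adjusted over the list alone, median −0.20, adjusted p = 0.00143, and adjusted p = 0.728 with an estimated correlation).

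The photosynthesis genes again passed higher, with 14 of 67 risen and 0 fallen (12 and 0 adjusted over the list alone). The median was 0.81, with adjusted p = 1.6e-06, and adjusted p = 0.61 with an estimated correlation. So did antioxidant enzymes (16 and 1 of 41, 17 and 1 adjusted over the list alone). The median was 0.25, with adjusted p = 0.00116, and adjusted p = 0.143 with an estimated correlation. An example was 2-Cys peroxiredoxin 2 (2-CP2) at 0.75 ± 0.10. Auxin genes rose in 44 of 152 and fell in 18 (51 and 20 adjusted over the list alone). The median was 0.31, with adjusted p = 0.0103, and adjusted p = 0.461 with an estimated correlation. Cell cycle and histone genes rose in 29 of 190 and fell in 6 (25 and 6 adjusted over the list alone). The median was 0.20, with adjusted p = 0.0405, and adjusted p = 0.728 with an estimated correlation. An example was the kinesin gene KIN-UC (LOC101268735) at 1.20 ± 0.14. Without K23 36 the calls of LEA (adjusted p = 0.0532) and cell cycle genes (adjusted p = 0.0959) were lost. Without K23 38 those of glutathione S-transferases (adjusted p = 0.05), cell cycle (adjusted p = 0.0785) and ribosomal protein genes (adjusted p = 0.226) were lost, and without K23 plus salt 81 those of cell cycle (adjusted p = 0.371) and ribosomal protein genes (adjusted p = 0.0944). The remaining lists did not pass, abscisic acid genes being the nearest (18 lower and 9 higher of 66, adjusted p = 0.0682). Pathogenesis-related and protease inhibitor genes, which passed lower without K23, were among them. The former had 14 higher and 14 lower of 123 (11 and 10 adjusted over the list alone, median −0.13, adjusted p = 0.602) and the latter 1 and 5 of 43 (0 and 2 adjusted over the list alone, median −0.29, adjusted p = 0.205). The median, mean and test differed in sign for root markers, aquaporins and heat shock genes, and the sign of these medians and that of sugar genes also flipped under another scaling.

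Both salt effects were compared gene by gene; they share no library. They had 1698 genes higher and 1496 lower in common, against 344 and 313 for independent lists of these sizes, and 3 genes were called in opposite directions each way. Without control 6 the 1698 became 1062. Of the 4708 genes called without K23, 96.5% had the same sign with K23, and their slope was 0.786. Across all genes, which are not independent replicates, Pearson's r was 0.711 and Spearman's rho 0.683.

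**Figure D4:**
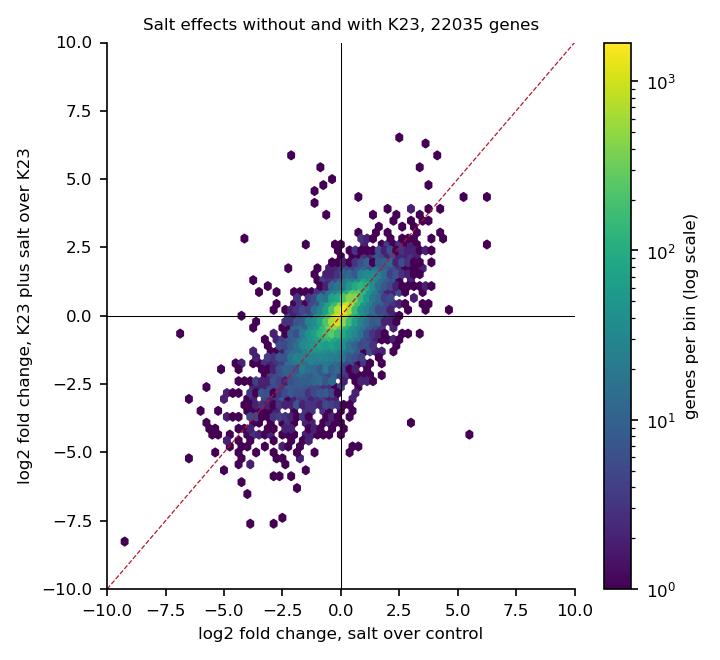
Salt effect of each of 22035 genes without K23 (horizontal axis, log2 fold change) and with K23 (vertical axis, log2 fold change), as hexagons shaded by the number of genes. The effects ran together across genes, with r = 0.711.

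Without salt, K23 raised a nitrate reductase gene and 2 genes of xyloglucan-modifying enzymes and lowered a gibberellin receptor gene. Nitrate reductase (NR; chromosome 11, 7177363 to 7181480), the first enzyme of nitrate assimilation, stood at 3.69 ± 1.54 CPM in the controls and 76.9 ± 52.1 in K23 (4.38 ± 0.55, adjusted p = 0.00587). The wall-remodelling genes LOC101258926 and XTH3, xyloglucan endotransglucosylases, rose from 33 ± 2.9 to 102 ± 18.2 CPM (1.62 ± 0.18) and from 26.1 ± 1.39 to 91 ± 24.3 CPM (1.80 ± 0.21, adjusted p = 0.00512 for each). The gibberellin-degrading 2-oxidase gene GA2ox3 rose from 9.26 ± 1.97 to 34.3 ± 8.62 CPM (1.89 ± 0.27, adjusted p = 0.00722). The gibberellin receptor gene GID1 (chromosome 9, 66483420 to 66484709) fell from 32.5 ± 4.95 to 13.5 ± 2.9 CPM (−1.27 ± 0.20, adjusted p = 0.0107).

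K23 without salt raised 468 genes and lowered 465 (edgeR, median SE 0.196), 284 and 142 of them by at least 1 on the log2 scale. Scaling by library totals alone, which moved the median of all genes from −0.01 to 0.10, called 710 higher and 243 lower. DESeq2 called 1182 and 1033, and a fit on the compared groups only 218 and 231. The other large rises were a patatin-like gene (LOC101260531, 4.59 ± 0.80), ERF016-like (LOC101268766, 4.56 ± 0.74), LE25 (4.31 ± 0.83), a LEA-type protein, a protein phosphatase 2C gene (LOC101258071, 4.13 ± 0.58) and a LEA gene (LOC100750252, 3.83 ± 0.95). The large falls were TIP3-2-like (LOC101251154, −3.69 ± 0.88), with an SD in the controls of 25.4 around a mean of 26.2 CPM, B-box protein 20 (LOC101247171, −3.32 ± 0.82), a purine permease (LOC101244659, −2.64 ± 0.33), a sulfite exporter family gene (LOC101251260, −2.33 ± 0.34), and the cytochrome P450 genes LOC101259785 (−2.22 ± 0.28) and LOC101262074 (−2.04 ± 0.31). Asr2, an abscisic acid and ripening induced gene, rose by 1.79 ± 0.25 and the sodium transporter gene HKT1,1 (LOC101245180) by 0.98 ± 0.20. The jasmonate-conjugating enzyme gene JAR1 (LOC101262053) fell from 152 ± 0.674 to 86.3 ± 2.78 CPM and the chitin-receptor family gene LysM receptor-like kinase 12 (LOC100736485) from 7.08 ± 1.26 to 2.13 ± 0.422. The number of genes called, 933, rested on single libraries: it was 561 without control 6, 65 without control 7, 586 without salt 53, 140 without K23 36 and 150 without K23 38. Of the 51 genes named by rule for this comparison, 14 kept their call in every refit that tested them, with other tools, scalings, filters and lines, on the compared groups only and without each library, among them NR, GA2ox3, LOC101258926, XTH3, JAR1 and LOC100736485. The GID1 call was lost without K23 36 (adjusted p = 0.0503), and that of TIP3-2-like without any 1 of 7 libraries and in the fit on the compared groups only (adjusted p = 0.0522). When 1 library was left out, the call of B-box protein 20 was lost in 8 refits and that of the LEA gene LOC100750252 in 7. Those of LE25 and HKT1,1 were lost in 4 each and that of the patatin-like gene in 2.

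Of the lists, 5 passed higher and 1 lower for K23 without salt, none with an estimated correlation (smallest adjusted p = 0.654), and fry passed 0 lists. The K23 libraries also enter salt with K23 and the interaction. A list high in these 3 libraries alone rises here and falls in both of those, so such calls are not separate results. NAC factors had median log2 levels, relative to the mean of the 12 libraries, of 0.38, 0.29 and 0.23 in K23 36, 37 and 38. In controls 6, 7 and 8 they were 0.24, −0.03 and −0.05. Of 95 class III peroxidases 3 rose and 0 fell (11 and 0 adjusted over the list alone). The median was 0.29, with adjusted p = 0.00196, and adjusted p = 0.654 with an estimated correlation. Peroxidase 70-like (LOC101268440) went from 28.1 ± 1.47 to 47.8 ± 3.11 CPM. Of 316 cell wall genes 10 rose and 3 fell (10 and 3 adjusted over the list alone). The median was 0.20, with adjusted p = 0.00212, and adjusted p = 0.705 with an estimated correlation. Of 53 NAC factors 3 rose and 0 fell (3 and 1 adjusted over the list alone). The median was 0.35, with adjusted p = 0.0107, and adjusted p = 0.654 with an estimated correlation. An example was NAC22 (LOC101267943) at 2.23 ± 0.42. Of 36 LEA genes 4 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.34, adjusted p = 0.0107, and adjusted p = 0.654 with an estimated correlation), and of 70 WRKY factors 3 rose and 1 fell (3 and 1 adjusted over the list alone). The median was 0.22, with adjusted p = 0.0264, and adjusted p = 0.827 with an estimated correlation. An example was WRKY48 (LOC101264826) at 2.71 ± 0.32. The photosynthesis genes passed lower with no member called in edgeR (0 of 67, and 0 adjusted over the list alone). The median was −0.58, with adjusted p = 1.1e-05, and adjusted p = 0.827 with an estimated correlation. Without control 8 the calls of photosynthesis (adjusted p = 0.142), LEA (adjusted p = 0.0641), NAC (adjusted p = 0.101) and WRKY genes (adjusted p = 0.393) were lost. So were those of WRKY genes without K23 38 (adjusted p = 0.175) and of cell wall genes without control 6 (adjusted p = 0.0522). The remaining lists did not pass; gibberellin genes had 2 higher and 5 lower of 34, with a median of 0.07, a mean of −0.17 and a test in the lower direction (adjusted p = 0.316). Median, mean and test also differed in sign for root marker, seed storage, abscisic acid, sodium and potassium transport, glutathione S-transferase, and phosphate and iron genes.

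Under salt, K23 raised 9 genes and lowered 8 (edgeR, median SE 0.196), of which 7 and 4 changed by at least 1 on the log2 scale; DESeq2 called 412 and 256, and a fit on the compared groups only 1 and 0. The subtilisin-like protease gene sbt4b (chromosome 1, 82577871 to 82580204) rose from 13.2 ± 0.728 in salt to 44.1 ± 3.99 CPM in K23 plus salt (1.74 ± 0.12, adjusted p = 0.000137). Peroxidase 70-like (LOC101268440) rose from 6.15 ± 0.859 to 17.2 ± 2.89 CPM (1.48 ± 0.14, adjusted p = 0.00341) and peroxidase P7 (LOC101264425) from 22.5 ± 7.63 to 106 ± 38.6 (2.24 ± 0.31, adjusted p = 0.0224). GID1 fell from 29 ± 6.66 to 8.59 ± 0.934 CPM (−1.76 ± 0.20, adjusted p = 0.0115). The abscisic acid 8'-hydroxylase gene LOC101249565, of the enzyme that degrades abscisic acid, rose from 9.87 ± 2.14 to 28.1 ± 2.49 CPM (1.51 ± 0.21, adjusted p = 0.0224).

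Other genes raised by K23 under salt were a zeatin O-glucosyltransferase gene (LOC104648079, 1.35 ± 0.19), a pleiotropic drug resistance transporter gene (LOC101260345, 1.14 ± 0.14) and a polygalacturonase inhibitor gene (LOC101261838, 0.87 ± 0.12), whose class of protein blocks fungal pectinases. Genes lowered were a sulfate transporter gene (LOC101251560, −1.40 ± 0.19), the gibberellin-signalling gene scarecrow-like 3 (LOC101253266, −0.95 ± 0.14), USPL1 (LOC101255440, −0.93 ± 0.13), cellulose synthase-like G3 (LOC101251018, −0.80 ± 0.12) and a phospholipase A1 gene (LOC101268830, −0.80 ± 0.11). The 17 calls became 9 without salt 51, 4 without salt 53, 4 without K23 plus salt 81, 3 without 82 and 9 without 83. Of the 13 genes named by rule, only sbt4b kept its call in every refit. The fit on the compared groups only lost the others, with an adjusted p of 0.106 for LOC101268440 and 0.0914 for GID1. The GID1 call was also lost without K23 plus salt 81 (adjusted p = 0.0559) or 82 (adjusted p = 0.0639).

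Of the lists, 4 passed higher and 2 lower for K23 under salt, none with an estimated correlation (smallest adjusted p = 0.22). Cell cycle and histone genes passed higher with 0 of 190 called over all genes and 59 higher and 2 lower adjusted over the list alone (median 0.35, adjusted p = 3.54e-15, and adjusted p = 0.342 with an estimated correlation). Ribosomal protein genes (219, median 0.17, adjusted p = 3.04e-07, and adjusted p = 0.631 with an estimated correlation) and pathogenesis-related genes (123, median 0.34, adjusted p = 5.25e-06, and adjusted p = 0.22 with an estimated correlation) passed with 0 members called in either way of adjusting. Protease inhibitor genes had 0 of 43 called, and 1 higher adjusted over the list alone (median 0.41, adjusted p = 0.0327, and adjusted p = 0.342 with an estimated correlation). Gibberellin genes passed lower with 2 of 34 fallen and 0 risen (7 and 5 adjusted over the list alone). The median was −0.28, with adjusted p = 0.0372, and adjusted p = 0.342 with an estimated correlation. The photosynthesis genes passed lower with 0 of 67 called (0 adjusted over the list alone). The median was −0.27, with adjusted p = 0.00851, and adjusted p = 0.841 with an estimated correlation. Over all genes, 3097 had an unadjusted p under 0.05, where 1102 are expected without any effect. The gibberellin call was lost without control 6 (adjusted p = 0.0538), control 8 (0.0591), salt 51 (0.0951), K23 plus salt 81 (0.143) or 82 (0.0707). The photosynthesis call was lost without salt 52 (adjusted p = 0.243), salt 53 (0.147) or K23 plus salt 83 (0.284), and the protease inhibitor call without salt 53 (adjusted p = 0.147), K23 plus salt 82 (0.0687) or 83 (0.174). The remaining lists did not pass, WRKY factors being the nearest (0 of 70 called, adjusted p = 0.0537), and the median, mean and test differed in sign for NAC, auxin, and recognition and resistance genes.

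The K23 effects without and with salt, which share no library, had 4 genes higher and 8 lower in common, against 0.2 for independent lists in each direction (one-sided Fisher's exact p = 2.33e-05 and 3.71e-14). This test treats genes as independent, and both comparisons share 1 estimate of the spread of each gene, so these p-values may be too small. The 4 became 1 without control 7, salt 53, K23 38 or K23 plus salt 82, and 2 without control 8, salt 51, salt 52, K23 36 or K23 plus salt 81. The 8 became 4 without control 7 or K23 36, 5 without salt 51 or K23 38, 2 without salt 53, 3 without K23 plus salt 83 and 0 without K23 plus salt 81 or 82. DESeq2 had 82 and 95 in common. Among the 8 genes lower in both were GID1 and scarecrow-like 3 (LOC101253266). Of the 933 genes called without salt, 79.7% had the same sign with salt, at a slope of 0.191. Across all genes, Pearson's r was 0.286 and Spearman's rho 0.337.

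The difference between both salt effects was tested as an interaction, with a median SE of 0.277. The gene sbt4b passed higher (1.42 ± 0.16, adjusted p = 0.0305): salt lowered it without K23 (−1.0 ± 0.12, adjusted p = 0.000224) and raised it with K23 (0.42 ± 0.11, adjusted p = 0.0173). LOC101248790 (chromosome 7, 12697824 to 12706611), which encodes a peroxisomal enzyme of fatty acid breakdown, passed lower (−2.12 ± 0.25, adjusted p = 0.0305). Its level was 40.7 ± 7.59 CPM in the controls, 32.6 ± 6.09 in salt, 154 ± 29.3 in K23 and 28.3 ± 1.65 in K23 plus salt. NR, at 2.91 ± 1.06 CPM in salt and 5.4 ± 2.5 in K23 plus salt, had an interaction of −3.50 ± 0.73 that did not pass (adjusted p = 0.151). In edgeR these 2 genes passed, 2039 had an unadjusted p under 0.05, and DESeq2 called 107 higher and 244 lower. The edgeR count was 11 without control 6, 3 without K23 37, 1 without K23 plus salt 83 and 0 without any of the other 9 libraries; the adjusted p of sbt4b reached 0.137 and that of LOC101248790 reached 0.15.

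**Figure D5:**
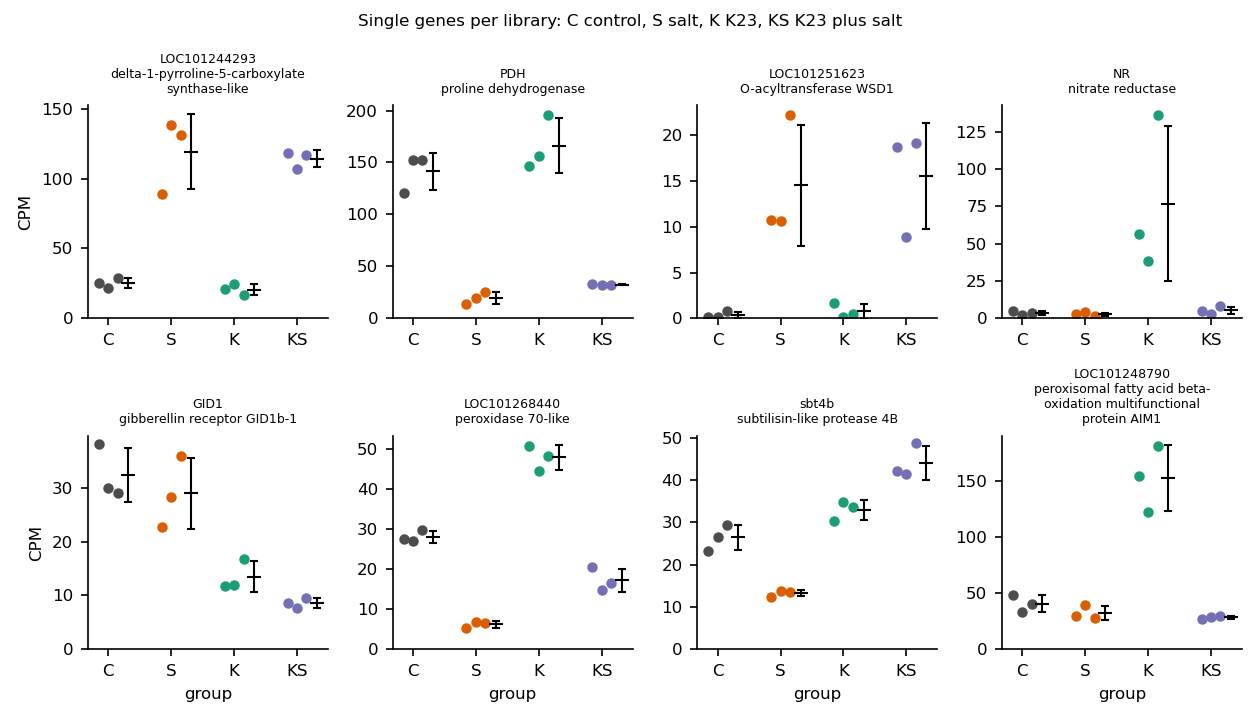
CPM of 8 genes in control (C), salt (S), K23 (K) and K23 plus salt (KS), 1 point per library with the mean ± SD of 3 libraries beside them. The mean of sbt4b was 13.2 CPM in salt and 44.1 in K23 plus salt, and that of LOC101248790 was 154 in K23 and 28.3 in K23 plus salt.

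For the interaction, 4 lists passed higher and 4 lower with 0 members called over all genes, and none with an estimated correlation (smallest adjusted p = 0.501). Cell cycle and histone genes (median 0.26, adjusted p = 0.000123, and adjusted p = 0.601 with an estimated correlation), pathogenesis-related (0.23, adjusted p = 0.0103, and adjusted p = 0.501 with an estimated correlation), photosynthesis (0.31, adjusted p = 0.0481, and adjusted p = 0.822 with an estimated correlation) and ribosomal protein genes (0.09, adjusted p = 0.0481, and adjusted p = 0.822 with an estimated correlation) passed higher, each with 0 members called adjusted over the list alone. Lower were NAC factors (median −0.34, adjusted p = 0.00382), heat shock (−0.15, adjusted p = 0.00382), LEA (−0.41, adjusted p = 0.00423) and osmolyte genes (−0.13, adjusted p = 0.0386), each with adjusted p = 0.501 with an estimated correlation. Adjusted over the list alone, 0 NAC, 6 heat shock, 1 LEA and 2 osmolyte genes were lower. The photosynthesis call was lost without control 7 (adjusted p = 0.318), salt 51 (0.737), K23 36 (0.0587), K23 plus salt 81 (0.257) or 82 (0.2), and turned to the opposite direction without control 8 (0.722) or K23 38 (0.897). The ribosomal call was lost without control 6 (adjusted p = 0.606), salt 51 (0.109), salt 53 (0.286), K23 36 (0.419), K23 37 (0.68), K23 plus salt 82 (0.572) or 83 (0.33), and with RLE scaling (0.0645). The osmolyte call was lost without salt 53 (adjusted p = 0.0662), K23 36 (0.0987) or K23 plus salt 81 (0.077), and the pathogenesis-related call without K23 37 (adjusted p = 0.116) or K23 plus salt 83 (0.148). Among the lists that did not pass, the median, mean and test differed in sign for seed storage, sodium and potassium transport, aquaporin and ethylene genes.

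The K23 effect without salt and the salt effect without K23 share the control libraries. They had 75 genes higher and 108 lower in common, against 50.4 and 49.3 for independent lists, and 63 and 82 in opposite directions, against 50 and 49.6. The fold changes had r = 0.036 and rho = −0.015 across genes. In 20 simulations all 12 libraries, controls included, were drawn from each gene's overall mean and spread, with genes independent and no group changed. Both comparisons shared the simulated controls and gave r = 0.507 and 66.9% of genes with the same sign. At most 1 gene was called and 0 were shared. The simulated controls lack the differences between the real controls that run across many genes. The observed covariance was 0.0164 and the simulated 0.0611, a difference of −0.0447. The 75 became 33 without control 6, 3 without control 7, 40 without salt 52, 46 without salt 53, 11 without K23 36 and 17 without K23 38. The 108 became 59 without control 6, 10 without control 7, 19 without K23 36, 71 without K23 37 and 20 without K23 38, and DESeq2 had 197 and 256 in common. Part of the shared calls may come from the shared controls, which are too few to be divided.

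The authors' deposited table of genes with a log2 fold change of at least 2 named 455 genes as up and 192 as down for control against salt, and 689 and 136 for K23 against K23 plus salt. For control against K23 the authors' deposited table named 43 and 169, and for salt against K23 plus salt 11 and 29. Over the 4 pairs, 1708 entries of the authors' deposited table were fitted here, where a gene listed for several pairs counts once in each. Of these entries 1707 had the opposite sign, since the deposited values divide the first named group by the second. The negated values correlated at r = 0.998 across entries. Of the up genes in the authors' deposited table, 426, 636, 25 and 1 were called lower here in the second group of the 4 pairs, and of the down genes 182, 120, 116 and 1 were called higher. For salt against K23 plus salt, 10 of the 11 up genes and 28 of the 29 down genes in the authors' deposited table did not pass here. DESeq2 called 30 genes of the authors' deposited table for this pair, against 2 in edgeR, which became 4 without salt 51 or K23 36, 1 without salt 52, salt 53, K23 plus salt 81 or 83, and 0 without 82. For control against K23, the genes of the authors' deposited table called here became 92 without control 6, 25 without control 7, 93 without control 8, 35 without K23 36 and 44 without K23 38.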

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

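The splits of the libraries and the tests of the spread and of single libraries were planned before the counts of genes were seen. The held-out test of the K23 effect was chosen only after the result was seen.

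Genes and lists whose salt effect differed between seedlings with and without K23, by the test of the difference itself, call for a closer look. The gene sbt4b had an interaction of 1.42 and LOC101248790 one of −2.12 on the log2 scale. Both lost their call in edgeR without any 1 of 10 libraries, all except control 6 and K23 37. The lists that differed had median interactions of 0.314 for photosynthesis, 0.232 for pathogenesis-related, 0.259 for cell cycle and histone and 0.091 for cytosolic ribosomal protein genes. The medians were −0.406 for LEA, −0.129 for osmolyte, −0.154 for heat shock and −0.338 for NAC genes. None of these lists passed with an estimated correlation or with fry.

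Other splits of the same libraries were counted for each comparison. For the 4 comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 4708 genes for salt without K23, 6148 for salt with K23, 933 for K23 without salt and 17 for K23 with salt. The highest of the other splits gave 0, 0, 2 and 0, so that in each comparison 1 split, the real one, gave as many. For the interaction, 9 of 100 splits gave at least the 2 genes of the real one, so chance cannot be excluded as the source of its count. The highest of these gave 1481 genes. It swaps the labels of salt and K23 plus salt, which turns the contrast into the sum of both K23 effects, so a K23 effect gives such calls and this split is no random grouping. Chance cannot be excluded without this split either. A second split gave 464. In it 2 of the control and K23 libraries and 4 of the salt and K23 plus salt libraries kept their label. It thus also turns the contrast partly into the sum of both K23 effects. Other splits with these numbers of kept labels gave 0 or 1 gene, and the cause of the 464 was not tested further.

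K23 changed 933 genes without salt and 17 with salt in edgeR, but 2215 and 668 in DESeq2, so the size of this gap depends on the tool. A K23 effect of equal size in both conditions may still give unequal counts. To avoid the genes' selection, genes were picked on 2 control and 2 K23 libraries and measured in the pair held out. Their mean change with salt was a median 0.24 of that in the held-out pair, from 0.176 to 0.45 over 9 pairs. This argues against an equal effect of K23 on these genes. No genes were picked on the libraries with salt, so an effect of equal size on other genes under salt stays open. The dispersion with salt was 0.927 of that without, which argues against a wider spread between the salt libraries. The part of 1 library stays open, since 65 genes were called for K23 without salt when control 7 was left out, and control 7 took part either in picking the genes or in the held-out pair of each of the 9 pairs.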

How the results depend on the processing

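Alternatives chosen only after the data were seen were the line with the fewest counts per gene, no plastid or mitochondrial genes, and lists without members that only share a word. With these, 25 of 25 counts stayed within 1.5 times and 46 of 47 list calls were kept. For named genes, both filters and the fit on the compared groups only were also added after the data were seen. All values added for named genes kept 928 of 956 past the threshold, and the 28 others were lost in the fit on the compared groups only. No paired analysis was possible because the count columns carry no replicate number (only group names and library numbers), so the replicate block was not run. The other alternatives kept 89 of 123 counts within 1.5 times, 574 of 579 values of named genes past the threshold and 68 of 141 list calls, and the cause of the changes was not tested except where stated.

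A log2 fold change of at least 1, which is a stricter demand, left 841 genes higher and 1194 lower for salt without K23, 882 and 1517 for salt with K23, 284 and 142 for K23 without salt, and 4 lower for K23 with salt. DESeq2 called 1182 and 1033 genes for K23 without salt, 412 and 256 for K23 with salt, and 107 and 244 for the interaction, and included 932 of the 933 edgeR calls for K23 without salt and 17 of 17 with salt. In DESeq2, 82 genes were higher and 95 lower in both K23 effects, 197 higher and 256 lower in both the K23 and salt effects, and 30 genes of the authors' deposited table were called for K23 with salt. Library totals alone called 710 and 243 genes for K23 without salt and 26 higher with salt, 8 of them higher in both. This scaling moved the median of all genes to 0.10 for K23 without salt and 0.095 with salt, and the share of higher calls from 50.2 to 74.5% and from 52.9 to 76.5%. In DESeq2 30.5% of the interaction calls were higher, against 50%. A fit on the compared groups only, with fewer libraries to estimate the spread, called 218 and 231 genes for K23 without salt and 1 and 0 with salt. With an estimated correlation 0 lists passed in each of the 5 comparisons, and with fry 13 passed for salt without K23, 14 for salt with K23, and 0 for K23 without salt, K23 with salt and the interaction.

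Without 1 library at a time, genes higher and lower ranged from 1360 to 2658 and 1593 to 2635 for salt without K23, 1762 to 3188 and 1893 to 3270 for salt with K23, 34 to 537 and 31 to 643 for K23 without salt, 2 to 15 and 0 to 10 for K23 with salt, and 0 to 1 and 0 to 10 for the interaction. Genes in both salt effects ranged from 1062 to 1658 higher and 1115 to 1448 lower, in both K23 effects from 1 to 3 and 0 to 8, and in K23 and salt from 3 to 91 and 10 to 154. Genes of the authors' deposited table called here ranged from 521 to 616, 634 to 780, 25 to 145 and 0 to 4. Lists passing ranged from 11 to 15, 10 to 14, 2 to 8, 5 to 10 and 5 to 9. Of single values, 2069 of 2316 for named genes and 514 of 564 for lists stayed past the threshold, and 2 reversed, both for the interaction of photosynthesis genes (adjusted p = 0.722 without control 8 and 0.897 without K23 38, in a range from 6.9e-11 without control 6). Some genes lay near the floor of 3 counts in a compared group, such as ERF020-like (LOC101257505), and a limit by depth was not tested.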

Other observations

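The gene groups in the next 2 paragraphs, the gibberellin and clock sets and all their tests were chosen only after values had been seen. The groups were tested for excess calls by 100 one-sided Fisher's exact tests of 10 groups in 5 comparisons with Benjamini-Hochberg adjustment. These tests treat genes as independent, and no test that allows for genes moving together was run on the groups. Where genes of a group move together, these p-values are too small. The groups were chosen after the calls that the tests count had been seen, so these p-values are no independent support.

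Genes of 2 calcium groups were called higher for K23 without salt more often than other genes. Of 14 calcium pump genes 6 rose and 0 fell (adjusted p = 3.85e-06), among them the plasma membrane pump gene LOC101262099, from 89.8 ± 11.9 to 162.9 ± 16.7 CPM (0.86 ± 0.14), and LCA1 of the endoplasmic reticulum, at 0.95 ± 0.23. Of 50 calcium-binding and calmodulin-like genes 7 rose and 0 fell (adjusted p = 0.000941), with CML30 (LOC101249625) from 9.71 ± 1.72 to 42.5 ± 14.9 CPM. With salt, 15 of the 50 fell and 1 rose without K23 (adjusted p = 0.00141 for the fall), and 26 fell and 1 rose with K23 (adjusted p = 1.65e-09). Of the pump genes 7 fell and 2 rose with K23 (adjusted p = 0.00925), while 2 rose and 2 fell without K23. The K23 effect without salt shares the K23 libraries with the salt effect with K23, so that a high level in these 3 libraries alone gives a rise in one and a fall in the other, and it shares the controls with the salt effect without K23. Under salt, 0 genes of either group were called for K23. Only 17 of all 22035 genes were called there, so this says little about calcium genes. The medians were −0.23 for the pump genes and −0.03 for the calcium-binding genes. For K23 without salt, of 12 growth-regulating factor genes, which promote leaf growth, 4 fell and 0 rose (adjusted p = 0.000941), with GRF3-like (LOC101268132) at −0.89 ± 0.19. The photosynthesis genes, a marker of shoot tissue, had a median of −0.58 in the same comparison (camera, adjusted p = 1.1e-05). The root tissue markers had a median of −0.10 there (0.008 when scaled by library totals alone) and did not pass. The part of a smaller share of shoot tissue in the fall of the growth-regulating factors was not tested. Of 99 sulfate and nitrate genes 7 fell and 4 rose for K23 without salt (adjusted p = 0.0358 for the fall), and NR was among those that rose. The 7 became 0 without control 7, 1 without K23 36 and 2 without K23 38. Autophagy genes and DnaJ and BAG chaperones passed in no comparison, and peroxisomal genes passed through 1 gene, LOC101248790, in the interaction (adjusted p = 0.029). The counts for K23 rested on single libraries. The 6 pump genes became 4 without control 6, 0 without control 7, 3 without control 8, 3 without salt 53, 1 without K23 36, 2 without K23 37, 1 without K23 38 and 4 without K23 plus salt 82. With salt, the 15 calcium-binding genes became 11 without control 7 or salt 51, the 26 became 21 without K23 plus salt 82, and the 7 pump genes became 5 without K23 plus salt 82. The 7 calcium-binding genes raised by K23 became 4 without control 6, 2 without control 7, 3 without control 8, and 2 without K23 36 or K23 38. The 4 growth-regulating factors became 0 without control 7, control 8, K23 36 or K23 38, 1 without salt 53, and 2 without K23 37, K23 plus salt 82 or 83.

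With salt, wax and cuticle genes were called higher and G-type lectin receptor kinases lower more often than other genes. Of 74 cuticle and wax genes 31 rose and 10 fell without K23 (adjusted p = 1.27e-10 for the rise), and 23 rose and 9 fell with K23 (adjusted p = 0.00197). This group was found by words that include WSD1 and non-specific lipid-transfer, so it holds the WSD1 gene named above and lipid-transfer proteins of any role. A fatty acyl-CoA reductase gene (LOC101260469), of an enzyme that makes fatty alcohols, rose from 4.19 ± 1.22 to 37.9 ± 3.85 CPM without K23, and the 3-ketoacyl-CoA synthase gene LOC101262858 by 1.32 ± 0.15. Of 64 G-type lectin receptor kinase genes 22 fell and 5 rose without K23 (adjusted p = 4.54e-06 for the fall), and 34 fell and 2 rose with K23 (adjusted p = 1.51e-12), with LECRK3 (LOC101267468) from 48.8 ± 9.68 to 6.95 ± 1.63 CPM with K23. Beside the photosynthesis list, 309 of 1152 plastid-targeted protein genes rose and 69 fell without K23 (adjusted p = 3.8e-54 for the rise), and 408 rose and 85 fell with K23. The photosynthesis list, a marker of shoot tissue, had medians of 0.47 without K23 and 0.81 with K23 in these comparisons. With an estimated correlation this list did not pass (camera, adjusted p = 0.774 without K23 and 0.61 with K23). The root tissue markers had medians of −0.03 without K23 and 0.03 with K23 and passed in neither comparison. The part of a larger share of shoot tissue in the changes of these groups was not tested. The 31 cuticle genes became 20 without control 6 or control 7, and the 34 lectin kinases 22 without K23 38 or K23 plus salt 82. The 309 plastid-targeted genes became 153 without control 6, 201 without salt 51 and 181 without salt 53, and the 408 became 241 without K23 36 and 210 without K23 38.

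Genes of gibberellin feedback moved with K23. The mean of 11 genes that gibberellin represses, less that of 11 that it induces, was −2.02 without salt and −2 with salt. Both values lay below all of 10000 random sets. Both gene sets were built after values had been seen and hold GID1, GA2ox3 and scarecrow-like 3, named above, while the random sets hold unrelated genes. This rank is therefore no independent support. The gibberellin list fixed beforehand, which holds genes of both kinds, did not pass for K23 without salt and passed lower with salt. A candidate explanation is more active gibberellin in seedlings with K23. The biosynthesis gene 20ox-3 stood at 3.94 CPM in the controls, 0.149 in K23, 2.34 in salt and 0.215 in K23 plus salt, and 7 of the 11 repressed genes were called lower without salt and 3 with salt. Of the 11 induced genes only 2 were called higher without salt and 0 with salt, with medians of 0.17 and 0.44, so the difference rests mainly on the repressed genes. The 7 became 4 without control 6 or K23 38, 3 without control 7 and 2 without K23 36, and the 3 became 0 without K23 plus salt 81 or 82 and in the fit on the compared groups only. The difference itself stayed between −2.11 and −1.87 without salt and between −2.12 and −1.85 with salt when 1 library was left out. The 6 repressed genes with a mean of at least 5 CPM had a median of −1.13 without salt and −1.05 with salt, which argues against counting noise. For a smaller share of shoot tissue, a first test, on the repressed genes under salt (median 0.22), decided nothing, and the test that replaced it, after that outcome, was barely under its bound of 5%: 4.5% of photosynthesis genes lay below the median of the repressed set without salt and 0% with salt. This argues against shoot share as the whole source, though weakly, and hormone levels were not measured. The root tissue markers had medians of −0.104 without salt and −0.085 with salt and passed in neither K23 comparison.

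Clock genes moved with salt: 9 evening genes less 8 morning genes stood at 0.65 without K23 (percentile 98.3 of 10000 random sets) and 1.46 with K23 (percentile 100). The morning gene LHY (LOC101261662) fell by 0.64 and 1.34 on the log2 scale and an evening APRR1 gene (LOC101259425) rose by 0.89 and 1.09. A second APRR1 gene (LOC101259163) stood at −0.14 and −0.20 and was not called. Without K23, edgeR called 3 of the 9 evening genes higher and 0 lower, and 4 of the 8 morning genes lower and 1 higher. With K23 the counts were 6 and 0, and 6 and 1. The morning gene called higher was REVEILLE 6 (LOC101259846), at 0.46 and 0.55. Salt seedlings collected at another time of day and a salt effect on the clock cannot be told apart, since both predict this difference and the labels give no hour of collection. For K23 without salt the difference was −0.24 (percentile 18.73). A first bound took a value inside the random range as evidence against another hour for the K23 seedlings, and was dropped because it cannot exclude a small shift. The K23 libraries stood at −0.9, −0.44 and −0.6 and the controls at −0.54, −0.5 and −0.06, so this stays open. For K23 with salt the difference was 0.57 (percentile 99.99) and for the interaction 0.81 (percentile 99.98), which may reflect the hour or the fungus. In both, edgeR called 0 members of either set. The clock sets were built after values had been seen, and the random sets hold unrelated genes. The percentiles of the clock sets are therefore no independent support.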
